A study of Mus musculus with 16 samples.

How the data were processed

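The samples were 16 RNA sequencing libraries of small intestinal organoids, epithelial cultures grown from the stem cells of intestinal crypts, of C57BL/6 mice at day 3 of culture. They fell into 4 groups of 4: organoids with Atg16l1 flanked by loxP sites (f/f, the wild-type group of the series) and ATG16L1-deficient organoids (dIEC), each unstimulated or given 20 ng/ml murine tumour necrosis factor (TNF) for 2 hours. The titles gave each sample's genotype, treatment and a number from 1 to 4. Total RNA was extracted with TRIzol and made into libraries by an Illumina protocol, per the labels' protocols. No label names the animal, culture, library batch or sequencing run of a sample, so p-values measure only the spread between these samples, which may be technical.

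The authors' deposited table gives 1 FPKM value (fragments scaled to transcript length and to the mapped fragments of the library) per gene and sample. TopHat2 2.1.1, Cufflinks 2.2.1, Cuffdiff and the mouse build mm10 are named per the submitters' processing notes, without their order or settings. How reads shared between genes were divided, and whether strand was used, is not given in the sources used here. The deposited table also holds 3 columns of p-values made by the authors, which were used only as described among the other observations. All per-sample columns were used (0 left out). Total reads per library are unknown, and the FPKM values did not allow whole reads to be recovered, so no test on counts was run, no counting interval is given and the depth behind a value is unknown. Many genes were listed at exactly 0, which in FPKM can be a low level or a failed estimate.

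Of 23847 rows, 11097 with a mean of at least 1 FPKM over the 16 samples were kept, and 12750 fell below that minimum. A symbol could have several rows: 254 symbols took up 740 rows, of which 118 were kept, and the kept rows held 11029 distinct symbols. Each row was tested on its own and is called a gene below. Values were analysed as log2(FPKM + 1), so every log2 change understates the change of genes with few FPKM. limma 3.58.1 in R 4.3.3 fitted 1 mean per group to all 16 samples, with moderated variances and a mean-variance trend (residual degrees of freedom 12, prior degrees of freedom 2.52). The 5 contrasts, tested two-sided, were dIEC against f/f without TNF and with TNF, TNF against none in f/f and in dIEC, and the difference of the TNF responses (response in dIEC minus response in f/f). Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, with no minimum fold change. Every adjusted p of a gene is from limma and n is 4 per group. SE is the standard error of a log2 change and SD the standard deviation of FPKM.

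The groupings, the tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The design had assumed normalized read values of unspecified kind and provided for FPKM with the minimum used here. The 27 gene lists covered the NF-kB and TNF early response, type I and III interferon-stimulated genes, interferon-gamma-type GTPases, antigen processing and presentation, antimicrobial and acute-phase genes, cell death machinery, autophagy machinery without Atg16l1, lysosome, unfolded protein response, ATF4 targets, the NRF2 oxidative stress response, cholesterol biosynthesis, hypoxia and glycolysis, immediate early genes, proliferation, ribosomal proteins, a mitochondrial list and sex-linked genes. Cell type lists covered stem, Paneth, goblet, enterocyte, enteroendocrine and tuft cells, fetal-like epithelium, immune cells, and mesenchymal and endothelial cells. Of 678 listed symbols, 645 were in the table. The 22 lists for testing with at least 5 kept genes went through camera (limma) with a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast, and again with the correlation estimated from the data. For each list the genes called over all tested genes were counted, and again with p-values adjusted over the list alone. Where those counts were equal, 1 of them may be given.

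Named genes were, per contrast, Atg16l1, the 8 largest rises and 8 largest falls among called genes whose 4 values in one group all lay above the 4 in the other, and up to 4 genes of smallest adjusted p from each list that was called and from 7 lists regardless. Clone-type symbols were not named among the rises and falls. The text prints from the first 2 of each list. Other genes beside a small count in a list were chosen after their values were seen and are marked so. Those outside the rule were not tested under the alternatives.

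Gene positions come from GENCODE vM21 and RefSeq annotation of GRCm38 (mm10). GC content is of the longest transcript. The test was tried on data simulated with the means and spread of the 11097 genes. For dIEC against f/f without TNF, 82% of 100 genes planted at a log2 change of 0.5 and 95% of 100 at 1 were recovered (12 false calls). For the difference of responses the shares were 65% and 89% (8 false calls). A list planted at 0.3 was called for dIEC against f/f and 0 unchanged ones were, but genes were drawn uncorrelated, unlike many real lists.

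Whether equal sample numbers pair the samples was examined from the correlation of their deviations from group means. All 4 number pairs of untreated and treated dIEC samples exceeded 0.1 (0.118 to 0.419), as the rule asked. In f/f, 3 of 4 did (-0.0296 to 0.321). Across genotypes no groups met the rule, but 1 pair reached 0.311, so dIEC pairing is not settled. Alternatives were pseudocounts of 0.1 and 5, no minimum or a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, robust variance moderation, sample weights, a fit of only the 8 samples compared, the replicate number as a block, leaving out each of the 16 libraries, an added fold change minimum, and the estimated correlation for lists. Those chosen after seeing the data were summing rows of a symbol, leaving out small RNA genes, a block nested in genotype, leaving out 4 libraries that stood apart, and removing a trend with GC content per library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Single-gene results of a few genes that the rule named are not reported here, and these genes remain in the fits, the lists and the counts of called genes.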

Results

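Gene expression was measured by RNA sequencing in mouse small intestinal organoids of 2 genotypes, f/f and ATG16L1-deficient (dIEC), without stimulation or 2 hours after addition of TNF, an inflammatory cytokine. ATG16L1 is part of the enzyme complex that attaches LC3 proteins to membranes during autophagy. Each of the 4 groups held 4 libraries. The depth of the libraries is unknown. Their FPKM values summed to 494221 to 610125, and 10796 to 11144 genes per library reached 1 FPKM. Across genes, which are not independent replicates, log2 values of libraries of 1 group correlated with r from 0.964 to 0.984 (24 pairs), and those of different groups with r from 0.930 to 0.983 (96 pairs). No library was a copy of another.

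Non-epithelial RNA was low in all groups. None of the genes listed for immune cells reached the minimum mean, and their FPKM summed to 2.78 ± 0.444 in unstimulated f/f, 3.52 ± 0.392 in unstimulated dIEC, 3.10 ± 0.400 in f/f with TNF and 3.87 ± 0.419 in dIEC with TNF (SD, n = 4). Mesenchymal and endothelial genes summed to 22.8 ± 6.00, 22.3 ± 2.26, 26.6 ± 4.54 and 22.8 ± 4.43 FPKM in the same order, and 2 of them were kept. The mitochondrial list had 0 genes in the table. Of the sex-linked genes, the Y-linked Ddx3y lay between 11.8 and 16.1 FPKM and Xist between 0.0368 and 0.0793 in all 16 libraries. On the second principal component, which held 10.3% of the variance (the first held 42.7%), f/f library 1 and dIEC library 4 of both treatments stood apart from the other 12 libraries, with scores from -26.9 to -11.9 and a gap of 10.7. In these 4 libraries the deviation of genes from their mean fell with the GC share of the transcript (Spearman rho across genes from -0.804 to -0.727), and in the other 12 libraries it did not (rho from 0.0957 to 0.709).

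**Figure D1:**
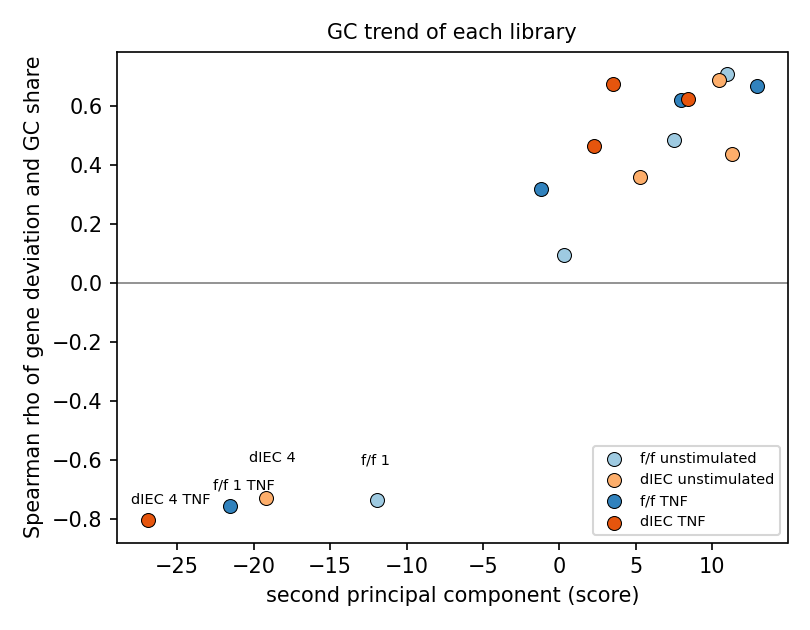
Each of the 16 points is a library, with its score on the second principal component of log2(FPKM + 1) on the horizontal axis and, on the vertical axis, the Spearman correlation across genes between GC share and deviation from the gene mean. The 4 named libraries lie at scores of -11.9 or lower with correlations of -0.727 or lower.

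Atg16l1 (chromosome 1, 87755870 to 87792428, plus strand, mm10) was lower in dIEC organoids in both treatments. Unstimulated, it measured 8.97 ± 0.472 FPKM in f/f and 5.64 ± 0.573 in dIEC (SD, n = 4), 62.9% of the f/f level, a log2 change of -0.59 (SE 0.0638, adjusted p = 0.000122). With TNF it measured 10.4 ± 0.679 and 7.24 ± 0.414 FPKM, 69.4% of the f/f level, a log2 change of -0.47 (adjusted p = 0.000233). All 4 dIEC values lay below all 4 f/f values in each treatment (exact two-sided permutation test, p = 0.0286 each, the smallest 4 against 4 can give). FPKM cover the whole gene, so reads from outside the deleted part can remain.

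**Figure D2:**
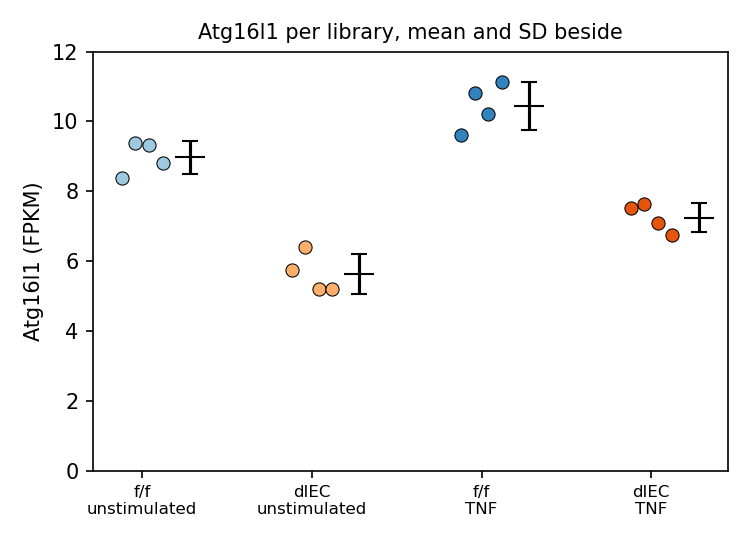
Points are the Atg16l1 FPKM of single libraries in the 4 groups, with the mean and SD (n = 4) of each group. In both treatments the 4 dIEC libraries lie below the 4 f/f libraries, with all 16 between 5.20 and 11.1 FPKM.

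The first comparison asked how ATG16L1-deficient organoids differed from f/f organoids without stimulation. Genes of the type I and III interferon response, which cells switch on against viruses, were higher in dIEC: 14 of 31 rose and 0 fell (20 rose adjusted over the list alone), with a median log2 change of 0.35. The count was 9 without unstimulated f/f library 3, f/f library 4 or dIEC library 2. Rtp4, an interferon-induced gene on chromosome 16 (23520291 to 23614222), went from 0.66 ± 0.116 to 3.85 ± 0.527 FPKM (SD, n = 4), a log2 change of 1.54 ± 0.149 (SE, adjusted p = 3.9e-05). Samd9l rose by 0.60 ± 0.0669 (adjusted p = 0.000144), and Oasl2, of the oligoadenylate synthetase family, by 1.21 ± 0.171 (adjusted p = 0.00131). Outside that list, the interferon-induced Ifi27l1 rose from 7.73 to 23.6 FPKM (adjusted p = 0.00085). The interferon list was called by camera (adjusted p = 3.25e-31, and 0.0419 with an estimated correlation). Of the 4 kept interferon-gamma-type GTPases, too few for the test, 3 rose (4 adjusted over the list alone): Irgm2, Igtp and, named after its values were seen, Ifi47 (0.36). Igtp and Irgm2 overlap on chromosome 11 (58199556 to 58207591 and 58199618 to 58222782), so how their reads were divided is uncertain, and Igtp was not called with a pseudocount of 5 (adjusted p = 0.162).

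Paneth cell genes, which encode the antimicrobial secretions of the crypt base, were lower in dIEC: 12 of 25 fell and 1 rose (14 and 1 adjusted over the list alone), with a median log2 change of -0.25 (camera adjusted p = 6.64e-18, and 0.019 with an estimated correlation). Mptx2, a mucosal pentraxin on chromosome 1 (173274382 to 173277777), fell from 40 ± 6.98 to 3.84 ± 1.19 FPKM, a log2 change of -3.10 ± 0.185 (adjusted p = 1.49e-07). The defensin gene Gm14851 on chromosome 8 (21095074 to 21096050) went from 585 ± 28.2 to 158 ± 31.1 FPKM (-1.90 ± 0.115). Defa20, named after its values were seen, was the riser (0.64). The listed defensins lie side by side on chromosome 8 (21025545 to 21735471) and are near-identical, so the division of reads among them is uncertain. Other large falls were of the X-linked Mid1, a ubiquitin ligase gene (chromosome X, 169685199 to 170005736), from 11.2 to 3.65 FPKM (-1.38 ± 0.0836), and of Fmr1nb (-2.90 ± 0.168). Zfp280c, a zinc finger gene on chromosome X (48541625 to 48594504), was listed at 0 in 6 of 8 f/f libraries and at 3.93 to 5.12 FPKM in the unstimulated dIEC libraries (adjusted p = 1.14e-11).

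Absorptive and antimicrobial genes were higher in unstimulated dIEC organoids. Of 26 enterocyte markers, 8 rose and 0 fell (12 adjusted over the list alone), among them Krt20 (0.38 ± 0.0672), with camera adjusted p = 5.97e-18 and adjusted p = 0.0109 with an estimated correlation. Without unstimulated f/f library 1, 2 or 4 or dIEC library 2 the risers numbered 4, and without f/f library 3 or dIEC library 1 or 4 they numbered 5. Of 13 antimicrobial and acute-phase genes 5 rose (7 adjusted over the list alone), led by the lectin gene Reg3a, from 257 ± 4.12 to 392 ± 32.7 FPKM (0.61 ± 0.0672, adjusted p = 0.000144). Pigr was among them (0.26, not called after quantile normalization, adjusted p = 0.142, or in a fit of the 8 samples, 0.104), as were, named after their values were seen, Reg3b (0.46), Nos2 (0.43) and Lypd8 (0.25). Of the antimicrobial genes 2 rose without unstimulated f/f library 2 or 4 or dIEC library 1, and 3 without f/f library 3 or dIEC library 2. That list had camera adjusted p = 3.72e-12, and 0.00835 with an estimated correlation. Of 26 cell death genes 0 were called, yet the list shifted up (median 0.07, camera adjusted p = 0.000161, and 0.0125 with an estimated correlation).

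The other lists called for this contrast lost the call with an estimated correlation. Of 26 antigen presentation genes 4 rose (6 adjusted over the list alone), led by Cd74, the invariant chain of MHC class II (0.98 ± 0.17; adjusted p = 0.0793 with a pseudocount of 5). For the antigen presentation list camera gave adjusted p = 1.08e-09, and 0.237 with an estimated correlation. The others were H2-Q1 (0.24) and, named after their values were seen, H2-Ab1 (0.72) and B2m (0.20). H2-Q1 was not called without unstimulated f/f library 3 (0.0641) or dIEC library 1 (0.0619). Of the list, 2 rose without unstimulated f/f library 2 or 3 or dIEC library 3, and 1 without dIEC library 1. Of 22 hypoxia and glycolysis genes 4 rose (10 adjusted over the list alone), the mitophagy gene Bnip3 by 0.56 ± 0.0908 and Egln3, an oxygen sensor, by 0.50 ± 0.0958, with P4ha1 (0.27) and Pfkfb3 (0.33) named after their values were seen. For the hypoxia list camera gave adjusted p = 2.18e-10, and 0.132 with an estimated correlation. Of the hypoxia genes 2 rose without any 1 of the unstimulated f/f libraries, unstimulated dIEC library 1 or 3, f/f library 2, 3 or 4 with TNF, or dIEC library 1, 2 or 3 with TNF. In a fit of the 8 samples alone Bnip3 (adjusted p = 0.0637) and Egln3 (0.124) were not called. Of 24 NF-kB genes, targets of the TNF pathway, 1 rose (1 adjusted over the list alone), the chemokine gene Ccl20 (0.37 ± 0.0726; adjusted p = 0.0612 in the fit of 8 samples), with list adjusted p = 0.000161 and adjusted p = 0.34 with an estimated correlation. The NRF2 list shifted up (adjusted p = 0.000257, and 0.237 with an estimated correlation) although its 1 called gene of 26, the heme-degrading Hmox1, fell (-0.59 ± 0.0981); adjusted over the list alone 1 rose and 1 fell. Stem cell markers shifted down (2 of 22 fell, 5 adjusted over the list alone, adjusted p = 6.27e-10, and 0.0779 with an estimated correlation). Those 2 were Slc14a1 (-0.56) and Cdca7 (-0.26), and 6 fell without unstimulated dIEC library 4. Slc14a1 was not called without unstimulated f/f libraries 1 (adjusted p = 0.0754), 2 (0.0679) and 4 (0.0954) or dIEC libraries 1 (0.0989), 2 (0.0567) and 3 (0.0774). Cdca7 was not called without unstimulated f/f libraries 2 (0.0922), 3 (0.0932) and 4 (0.0939) or dIEC libraries 1 (0.104) and 3 (0.0707). Proliferation genes shifted down with 0 of 29 called (0 adjusted over the list alone, adjusted p = 3.24e-06, and 0.0583 with an estimated correlation).

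Ribosomal proteins (0 of 28 called, adjusted p = 0.0227, and 0.684 with an estimated correlation), cholesterol biosynthesis (1 of 23 rose, Insig1, 0.18; adjusted p = 0.00522, and 0.424 with an estimated correlation) and enteroendocrine markers (2 of 18 rose, 5 with 1 fall adjusted over the list alone; adjusted p = 0.0368, and 0.424 with an estimated correlation) were called as lists, but each call rested on single libraries. The hormone gene Nts rose by 0.85 ± 0.126 (adjusted p = 0.00178) and Cpe by 0.27. Cpe was not called without unstimulated f/f libraries 1 (0.0823), 2 (0.0895) and 3 (0.0884) or dIEC libraries 1 (0.095), 2 (0.0585) and 4 (0.0652). Insig1 was not called without unstimulated f/f libraries 1 (0.108), 2 (0.0846), 3 (0.0607) and 4 (0.0918), unstimulated dIEC libraries 1 (0.105), 2 (0.107) and 4 (0.0792), f/f libraries 2 (0.0525), 3 (0.052) and 4 (0.0569) with TNF, or dIEC libraries 1 (0.0526) and 2 (0.056) with TNF. Without unstimulated f/f library 1 the adjusted p was 0.173 for ribosomal proteins, 0.0747 for cholesterol and 0.0558 for enteroendocrine markers. Ribosomal proteins also lost the call without unstimulated dIEC library 2 (0.117) and turned up without dIEC library 4 (0.686). Enteroendocrine markers lost it without unstimulated f/f library 2 (0.0506), dIEC libraries 1 (0.0682), 2 (0.0715) and 3 (0.0664), and TNF-treated f/f library 3 (0.0546), with no minimum mean (0.448), after median-of-ratios scaling (0.0604) and with the GC trend removed (0.074). Ribosomal proteins lost it after quantile normalization (0.065) and turned up without the 4 libraries apart on the second component (0.363). Not called were the autophagy (0 of 35 genes, adjusted p = 0.233), lysosome (0.576), unfolded protein response (0.917), immediate early (0.757), goblet (0.401), tuft (0.549), fetal-like (0.185) and ATF4 lists (0.0625). For the unfolded protein response, immediate early and fetal-like lists the median, mean and test differed in sign. The ATF4 list was called without unstimulated f/f library 1 (0.00923) or dIEC library 2 (0.0173), and the fetal-like list without f/f library 1 (0.0349). Other alternatives called the ATF4 list down, namely quantile normalization (0.0343), no minimum mean (0.0401) and removal of the GC trend (0.0457). The fetal-like list was called up without the 4 libraries apart on the second component (0.0287).

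In all, limma called 258 of 11097 genes in unstimulated dIEC against f/f organoids (171 higher, 87 lower), 19 of them with at least a doubling or halving. Over all 11097 genes, the 4 values of one group all lay above those of the other for 779 (7.02%), which chance gives for 2.86% of genes. With sample weights 1781 genes were called and the balance turned (582 higher, 1199 lower). Higher genes outnumbered lower ones with the GC trend removed (519 against 167, 686 in all), after median-of-ratios scaling (212 against 78) and after quantile normalization (159 against 66). Calls fell to 139 without unstimulated f/f library 2, 140 without f/f library 3, 142 without f/f library 4, 141 without dIEC library 1 and 153 without dIEC library 2. Without the 4 libraries that stood apart on the second component, a choice made after seeing the data, they were 709 (337 higher, 372 lower).

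With TNF, the second comparison asked how the genotypes differed during stimulation. Interferon-stimulated genes were higher in dIEC organoids in 30 of 31 cases with 0 lower (31 adjusted over the list alone), with a median log2 change of 0.92. Isg15, a ubiquitin-like antiviral protein (chromosome 4, 156199424 to 156200818), measured 6.27 ± 2.51 FPKM in f/f and 40.6 ± 15.9 in dIEC (SD, n = 4), a log2 change of 2.50 ± 0.285 (SE, adjusted p = 4.94e-05). Ifit1, which binds viral RNA, went from 1.73 to 13.1 FPKM (2.33 ± 0.188), Rtp4 by 2.02 ± 0.149 and Slfn2, outside the list, by 1.99 ± 0.141. The camera test gave adjusted p = 4.77e-50, and 0.0112 with an estimated correlation. All 4 kept GTPases were higher (4 adjusted over the list alone), with Igtp at 1.52 ± 0.129, Irgm2 at 1.20, and Irgm1 (0.81) and Ifi47 (0.64) named after their values were seen.

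Paneth cell genes were lower in TNF-treated dIEC organoids: 15 of 25 fell and 0 rose (18 adjusted over the list alone). For the Paneth list camera gave adjusted p = 6.35e-29, and 0.0112 with an estimated correlation. Mptx2 differed by -3.12 ± 0.185, and Defa21 and Defa22, of uncertain division as above, measured 143 ± 9.87 and 145 ± 9.83 FPKM in f/f against 43.6 ± 1.12 and 44.8 ± 2.79 in dIEC (log2 changes -1.69 and -1.67). Fetal-like and regenerative genes were higher, 8 of 12 (8 adjusted over the list alone), led by the surface proteins Ly6e, from 31 ± 1.92 to 65.8 ± 8.99 FPKM (1.05 ± 0.0768), and Ly6a (1.66 ± 0.13). For the fetal-like list camera gave adjusted p = 3.33e-12, and 0.0112 with an estimated correlation. NRF2 genes were higher, 14 of 26 with 0 lower (21 adjusted over the list alone), among them the antioxidant gene Srxn1 (0.50 ± 0.0422) and the glutathione transferase Gsta4 (0.66 ± 0.0607). For the NRF2 list camera gave adjusted p = 3.16e-18, and 0.0112 with an estimated correlation. Of 26 cell death genes 4 were higher (6 adjusted over the list alone; adjusted p = 0.000562, and 0.0125 with an estimated correlation). Mlkl, the pore-forming effector of necroptosis, measured 3.56 ± 0.25 FPKM in f/f and 6.31 ± 0.416 in dIEC (0.68 ± 0.0629, adjusted p = 6.84e-06). The others were the TNF receptor Tnfrsf1b (0.33) and, named after their values were seen, Pmaip1 (0.27) and Casp8 (0.23).

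The remaining lists called in this contrast lost the call with an estimated correlation. Of 24 NF-kB genes 6 were higher and 1 lower (9 and 1 adjusted over the list alone). Camera gave adjusted p = 4.92e-06, and 0.235 with an estimated correlation. Tnf went from 10.8 ± 1.28 to 17.1 ± 0.878 FPKM (0.63 ± 0.077) and the chemokine Cxcl16 was higher by 0.54 ± 0.0756. Cd83 (-0.45), named after its value was seen, was lower. Of 18 enteroendocrine markers 7 were higher (8 adjusted over the list alone), including Cpe (0.39) and Scg2 (0.46). Camera gave that list adjusted p = 1.16e-06, and 0.0544 with an estimated correlation. Enterocyte markers, higher in dIEC without TNF, were lower with it: 6 of 26 fell and 1 rose (9 and 2 adjusted over the list alone). For the enterocyte list camera gave adjusted p = 2.18e-06, and 0.101 with an estimated correlation. Without TNF-treated f/f library 3 the lower markers numbered 3, and without unstimulated f/f library 1 or TNF-treated dIEC library 4 the higher ones 2. Lactase, Lct, differed by -0.76 ± 0.072, while Alpi (0.49), named after its values were seen, was higher. Stem cell markers were lower (2 of 22, 4 adjusted over the list alone), namely Sox9 (-0.35) and Smoc2 (-0.21), and 6 were without unstimulated dIEC library 4. For the stem cell list camera gave adjusted p = 3.84e-05, and 0.235 with an estimated correlation. Smoc2 was not called without unstimulated f/f library 3 (0.0594) and dIEC library 1 (0.0513), or without f/f libraries 2 (0.0893), 3 (0.096) and 4 (0.127) and dIEC libraries 1 (0.105), 2 (0.0622), 3 (0.0611) and 4 (0.104) with TNF. Goblet markers were lower as a list (2 up and 2 down of 19, 2 and 6 adjusted over the list alone), with Zg16, a mucus lectin, at -0.49, Muc13 at 0.28 (adjusted p = 0.0542 after quantile normalization), and, named after their values were seen, Galnt12 at -0.24 and Klk1 at 0.31. The falls numbered 1 without unstimulated f/f library 3 or 4 or dIEC library 2 or 3, or f/f library 2, 3 or 4 or dIEC library 1 or 4 with TNF. For the goblet list camera gave adjusted p = 0.0163, and 0.279 with an estimated correlation. Proliferation genes were higher (2 of 29, 2 adjusted over the list alone), namely Ccnb1 (0.21; adjusted p = 0.0557 after median-of-ratios scaling and 0.0923 after quantile normalization) and Cdk1 (0.15), with 4 higher without unstimulated f/f library 1. For the proliferation list camera gave adjusted p = 0.0046, and 0.235 with an estimated correlation. Cdk1 was not called without TNF-treated f/f libraries 2 (0.0773), 3 (0.0969) and 4 (0.0663) or dIEC libraries 1 (0.0691), 2 (0.0682) and 3 (0.0937).

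Reg3b, an antibacterial lectin (chromosome 6, 78370657 to 78373466), measured 157 ± 18.1 FPKM in TNF-treated f/f and 45.2 ± 4.26 in dIEC (-1.77 ± 0.0958, adjusted p = 3.2e-08). The antimicrobial list went both ways, with 5 genes higher and 3 lower (7 and 4 adjusted over the list alone), and was not called (adjusted p = 0.0903). It was called up without TNF-treated f/f library 1 (0.0463), after median-of-ratios scaling (0.0248) and with no minimum mean (2.24e-06). Besides Reg3b the lower genes were Reg3a (-0.88) and Ido1 (-0.50), and the higher ones Nos2 (1.33), Duoxa2 (0.99), Duox2 (0.93), Lypd8 (0.52) and Dmbt1 (0.47), these 7 named after their values were seen. Antigen presentation was not called either (3 of 26 higher, 6 with 2 lower adjusted over the list alone; adjusted p = 0.0868), with B2m, the light chain of MHC class I, at 0.33 ± 0.0489, Psme1 at 0.34 and, named after its values were seen, Psme2 at 0.26. It was called up without TNF-treated f/f library 2 (0.0175), f/f library 3 (0.0239) or dIEC library 4 (0.00478). The same held after median-of-ratios scaling (0.0441) or quantile normalization (0.0404), with no minimum mean (0.0157), with the GC trend removed (0.0288) and without the 4 libraries apart on the second component (0.0245). Autophagy genes had 0 calls of 35 (adjusted p = 0.0868). The autophagy list was called down without TNF-treated f/f library 1 (0.0467), after quantile normalization (0.0465), with the GC trend removed (0.0221) and without the 4 libraries (0.0171). Also not called were the lysosome (0.942), unfolded protein response (0.43), cholesterol (0.911, with its median, mean and test of different sign), hypoxia (0.128; Ndrg1, named after its value was seen, was lower, -0.43; 2 genes were without treated f/f library 1) and ribosomal lists (0.487).

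A further 3 lists were called in this contrast. ATF4 targets were lower (3 of 21, or 3 with 1 higher adjusted over the list alone), namely Nupr1 (-0.77 ± 0.0735), Vldlr (-0.36) and, named after its values were seen, Stc2 (-0.65), and the call of the list was lost without TNF-treated dIEC library 4 (adjusted p = 0.101). For the ATF4 list camera gave adjusted p = 0.0107, and 0.531 with an estimated correlation. Immediate early genes were higher (3 of 15, 3 adjusted over the list alone), namely Atf3 (0.50), Fos (0.40) and, named after its values were seen, Klf6 (0.24). For the immediate early list camera gave adjusted p = 0.0472, and 0.531 with an estimated correlation. That call was lost without unstimulated dIEC libraries 3 (0.0505) and 4 (0.0545), f/f libraries 1 (0.177) and 3 (0.0812) with TNF, and dIEC libraries 1 (0.0854) and 2 (0.105) with TNF, with a pseudocount of 0.1 (0.0573), with the replicate block (0.0678) and without the 4 libraries apart on the second component (0.0918). Tuft markers were lower (1 of 9; 1 adjusted over the list alone; adjusted p = 0.0499, and 0.265 with an estimated correlation). The tuft call was lost without unstimulated f/f library 3 (0.0532) and dIEC libraries 3 (0.0505) and 4 (0.0545), and without TNF-treated f/f libraries 1 (0.0948) and 3 (0.0744) and dIEC libraries 1 (0.0631), 2 (0.0954) and 4 (0.0614). It was also lost with a pseudocount of 5 (0.0692), after median-of-ratios scaling (0.0527) or quantile normalization (0.186), with the replicate block (0.0517) and without the 4 libraries (0.0766). Mid1 (-1.64) was again lower, and Zfp280c lay at 3.68 to 4.66 FPKM in the dIEC libraries (adjusted p = 1.95e-11).

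With TNF, 721 of 11097 genes differed between genotypes (421 higher, 300 lower in dIEC), 54 of them by a doubling or halving at least. The share of higher genes was 58.4% as deposited, 50.6% after median-of-ratios scaling (360 higher, 352 lower) and 50.2% after quantile normalization (336 higher, 333 lower), so the size of that excess depended on the scaling. Over all 11097 genes, 1540 (13.9%) had groups that did not overlap, against 2.86% by chance. Calls numbered 1505 without the 4 libraries apart on the second component. In that fit 11 enterocyte markers fell and 2 rose.

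**Figure D3:**
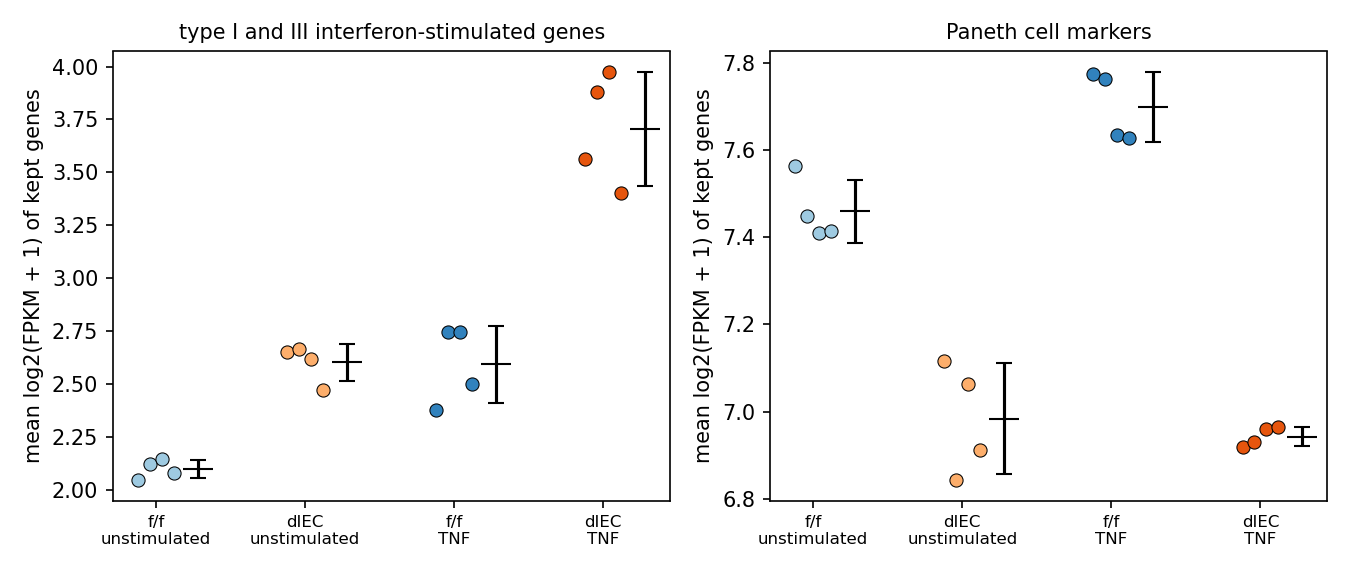
Each point is the mean log2(FPKM + 1) over the kept genes of a list in 1 library, for interferon-stimulated genes and Paneth cell markers in the 4 groups, with the mean and SD (n = 4). With TNF the interferon scores averaged 2.59 in f/f and 3.71 in dIEC, and the Paneth scores 7.70 and 6.94.

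The next comparisons asked what 2 hours of TNF changed within each genotype. Where 2 values stand together, the first is for f/f and the second for dIEC. NF-kB target genes rose in both genotypes, 23 of 24 in each (23 in f/f and 24 in dIEC adjusted over the list alone), with medians of 1.64 in f/f and 1.76 in dIEC. The chemokine gene Ccl20 (chromosome 1, 83116766 to 83119167) rose from 8.63 ± 0.969 to 244 ± 15.8 FPKM in f/f and from 11.4 ± 0.206 to 290 ± 23.7 in dIEC (SD, n = 4), log2 changes of 4.67 and 4.55 (SE 0.0726, adjusted p = 3.69e-16 and 5.32e-16). Tnfaip3, a feedback inhibitor of NF-kB, rose by 2.92 and 2.91, and the adhesion molecule Icam1 by 3.51 and 4.04. The list had camera adjusted p = 3.4e-18 and 3.99e-16, and 0.0687 and 0.189 with an estimated correlation. No list was called for either TNF contrast with an estimated correlation (0 of 22 in each).

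Hypoxia and glycolysis genes rose with TNF, 21 of 22 in f/f and 20 with 1 fall in dIEC (adjusted over the list alone, 21 in f/f), with adjusted p = 2.26e-15 and 5.56e-10, and 0.128 and 0.189 with an estimated correlation. Pfkfb3, a regulator of glycolysis, rose by 3.13 and 2.73 (SE 0.0811), and Egln3 by 2.92 and 2.63. In dIEC the falling gene, named after its values were seen, was Pfkfb4 (-0.28), with 0 falls without unstimulated dIEC library 1, 2 or 3 or treated library 3 or 4, and 2 without unstimulated library 4. Stem cell markers rose, 19 and 20 of 22 (19 in f/f adjusted over the list alone), among them the stem cell transcription factor Ascl2 (2.32 and 2.40) and the receptor Tnfrsf19 (1.77 and 1.64). For the stem cell list camera gave adjusted p = 1.73e-08 and 1.42e-07, and 0.182 and 0.189 with an estimated correlation. Immediate early genes rose, 12 and 13 of 15 (13 in f/f adjusted over the list alone), including Atf3 (2.06 and 2.41) and the phosphatase Dusp1 (1.65 and 1.83). For the immediate early list camera gave adjusted p = 2.88e-07 and 1.38e-06, and 0.182 and 0.189 with an estimated correlation. Of 26 NRF2 genes 19 fell in f/f and 15 in dIEC, with 1 and 3 rising (20 and 1 in f/f adjusted over the list alone). For the NRF2 list camera gave adjusted p = 2.33e-12 and 2.81e-06, and 0.0687 and 0.189 with an estimated correlation. The glutathione transferase Gsta3 fell from 257 to 98.4 FPKM in f/f and from 259 to 110 in dIEC (-1.38 and -1.24, SE 0.0512). Hmox1 rose in both, by 2.39 in dIEC and, named after its value was seen, 1.38 in f/f, and the other risers in dIEC, likewise named, were Me1 (0.35) and G6pdx (0.13).

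Interferon-stimulated genes rose with TNF, 15 of 31 with 1 fall in f/f (17 and 1 adjusted over the list alone; adjusted p = 0.00054, and 0.736 with an estimated correlation) and 28 with 0 falls in dIEC (29 adjusted over the list alone; adjusted p = 2.38e-10, and 0.299 with an estimated correlation). Samd9l rose by 1.15 and 1.09 and Parp14 by 0.78 and 1.25, and the faller in f/f, named after its values were seen, was Epsti1 (-0.16). There were 0 falls in f/f without unstimulated f/f library 1, 2 or 3, unstimulated dIEC library 1 or 3, f/f library 1 or 4 with TNF, or dIEC library 1 or 3 with TNF. Of the 4 GTPases, 3 and 4 rose (3 and 4 adjusted over the list alone), such as Ifi47 (0.89 and 1.17). Antigen presentation genes rose, 15 of 26 with 2 falls in each genotype (15 and 3 in f/f, 16 and 4 in dIEC adjusted over the list alone), and in dIEC the call of the list was lost without unstimulated dIEC library 4 (adjusted p = 0.0819). For the antigen presentation list camera gave adjusted p = 0.00666 and 0.0298, and 0.736 and 0.665 with an estimated correlation. Cd74 rose by 3.99 in f/f, from 2.12 to 48.9 FPKM, and by 2.77 in dIEC, from 5.17 to 41.4 FPKM (SE 0.17), and H2-Ab1 by 3.26 and 2.28. The falling genes, named after their values were seen, were H2-Q1 in both (-0.13 and -0.21), Psme2 in f/f (-0.25) and H2-T3 in dIEC (-0.54), with 1 fall in f/f without unstimulated library 1, 2 or 4 or treated library 1, and 4 in dIEC without unstimulated library 4. Fetal-like genes rose, 7 of 12 with 1 fall in f/f and 10 with none in dIEC (adjusted p = 0.00613 and 6.97e-06, and 0.369 and 0.189 with an estimated correlation). Areg, an epidermal growth factor receptor ligand, rose by 1.59 and 1.91 (SE 0.0595), and the faller in f/f, named after its values were seen, was Clu (-0.49). In f/f the call of the fetal-like list was lost with the GC trend removed (adjusted p = 0.066).

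Cholesterol biosynthesis genes rose, 17 and 15 of 23 with 1 fall each, Ebp (-0.23 and -0.20, named after its values were seen), with adjusted p = 0.00096 and 0.0383, and 0.467 and 0.613 with an estimated correlation. Sqle rose by 0.49 and 0.51. There were 2 falls without treated f/f library 1 in f/f and treated dIEC library 4 in dIEC. In dIEC that call was lost without unstimulated dIEC library 4 (0.0581) and after median-of-ratios scaling (0.0601). Enteroendocrine markers rose in dIEC, 11 of 18 (12 adjusted over the list alone), such as Gcg, the glucagon gene (0.82), and were not called in f/f (7 up, 1 down, adjusted p = 0.276; 4 up without unstimulated f/f library 1, 0 down without library 1, 2 or 4 of either treatment). For the enteroendocrine list in dIEC camera gave adjusted p = 0.0159, and 0.375 with an estimated correlation. Ribosomal protein genes fell in 9 of 28 cases in f/f and 7 in dIEC (9 and 5 adjusted over the list alone), such as Rpl7 (-0.46 and -0.43). For the ribosomal list camera gave adjusted p = 0.00382 and 0.0298, and 0.736 and 0.665 with an estimated correlation. Their direction depended on the scaling: the medians of -0.18 and -0.11 became 0.03 and 0.08 after quantile normalization, which also ended the calls of Rpl7 (adjusted p = 0.0726 and 0.218). In dIEC that list was not called without unstimulated dIEC libraries 1 (0.0851) and 3 (0.095) or TNF-treated library 4 (0.1), and 12 of its genes fell without unstimulated dIEC library 4.

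Outside these lists, the calcium-binding gene S100g fell from 1856 to 316 FPKM in f/f and from 1951 to 313 in dIEC (-2.54 and -2.64, SE 0.12), and the carboxylesterase Ces1g by 2.52 and 2.70 on the log2 scale. The iron reductase Cybrd1 rose by 4.03 and 3.59. In dIEC, Nos2 rose from 0.942 to 31.5 FPKM (4.06 ± 0.0848), and Reg3b fell from 857 ± 102 to 45.2 ± 4.26 FPKM (-4.21 ± 0.0958). Mir684-1 and Rnaset2b, each with several table entries, passed the rule for large changes only because values changed places between entries from untreated to treated columns, and their changes are not reported as results. Atg16l1 rose by 0.31 in dIEC (adjusted p = 0.00081). In f/f its 0.20 (adjusted p = 0.0194) was not called without unstimulated f/f library 1 (0.0634) or TNF-treated f/f libraries 2 (0.0535) and 4 (0.0653).

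Several lists held genes that moved in both directions under TNF and were not called. Autophagy genes went up in 10 and down in 8 of 35 cases in f/f (11 and 8 adjusted over the list alone; adjusted p = 0.802) and up in 7 and down in 11 in dIEC (0.187), with the cargo receptor Sqstm1 rising by 0.99 and 1.07 and Wipi1 by 0.84 and 0.85. Cell death genes rose in 11 and fell in 5 of 26 cases in f/f (3 falls without unstimulated f/f library 2; 0.138) and rose in 12 and fell in 4 in dIEC (0.103), led by the BH3-only gene Pmaip1 (1.14 and 1.30). Paneth genes rose in 13 and fell in 3 of 25 cases in f/f (0.113), with Defa22 at 1.36, and rose in 9 and fell in 12 in dIEC (0.29), with Mptx1 at -1.15. In f/f the falling Paneth genes, named after their values were seen, were Mptx1 (-0.39), Gm14851 (-0.40) and AY761184 (-0.59). Enterocyte markers rose in 15 and fell in 5 of 26 cases in f/f (0.0789) and rose in 6 and fell in 10 in dIEC (6 and 11 adjusted over the list alone; 0.0557). Proliferation genes rose in 6 and fell in 6 of 29 cases in f/f (0.615) and rose in 18 and fell in 2 in dIEC (19 and 2 adjusted over the list alone; 1 fall without treated dIEC library 2; 0.052). With the replicate number as a block, which pairs samples by number, the proliferation list rose and the enterocyte list fell in dIEC (adjusted p = 0.0373 each). The others in f/f and dIEC had adjusted p = 0.424 and 0.113 (antimicrobial), 0.248 and 0.218 (lysosome), 0.342 and 0.262 (unfolded protein response), 0.223 and 0.404 (ATF4), 0.802 and 0.364 (goblet) and 0.704 and 0.632 (tuft). Median, mean and test differed in sign for the antimicrobial, autophagy and proliferation lists in f/f and the autophagy, goblet and tuft lists in dIEC.

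The alternatives changed some of these list results. In f/f, the Paneth list was called up without unstimulated f/f library 1 (adjusted p = 0.027) or TNF-treated f/f library 4 (0.0399), and the enterocyte list without the latter (0.0471). In dIEC, the proliferation list was called up without unstimulated f/f libraries 1 (0.0349) and 3 (0.0489), unstimulated dIEC library 3 (0.0498), f/f library 1 with TNF (0.0493), and dIEC libraries 1 (0.0394) and 2 (0.0499) with TNF. The enterocyte list was called down in dIEC without unstimulated dIEC library 3 (0.0498), f/f library 1 with TNF (0.0493) and dIEC library 1 with TNF (0.0394). After quantile normalization the enterocyte (0.00141), Paneth (0.00199), ATF4 (0.0104), lysosome (0.0249) and unfolded protein response lists (0.0342) were called up in f/f, and the proliferation (0.0112) and cell death lists (0.0466) in dIEC. With no minimum mean the enterocyte (0.0392) and Paneth lists (0.0474) were called up in f/f, the proliferation (0.0126) and cell death lists (0.0356) were called up in dIEC, and the enterocyte list was called down in dIEC (0.0299). In dIEC the proliferation list was also called up, and the enterocyte list down, with the block nested in genotype (0.0293 and 0.0302) and without the 4 libraries apart on the second component (0.0325 and 0.0409). Removing the GC trend called the proliferation list up in dIEC (0.0227).

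In all, limma called 5235 of 11097 genes in f/f (2986 up, 2249 down) and 5897 in dIEC (3702 up, 2195 down), of which 298 and 396 changed by a doubling or halving at least. The share of rises was 57% in f/f and 62.8% in dIEC as deposited, 48.8% and 49.1% after median-of-ratios scaling, and 45.2% and 46.5% after quantile normalization, so the balance of directions depended on the scaling. Between genotypes, 2591 genes rose in both (996 expected of independent lists) and 1734 fell in both (445 expected). A further 25 rose in f/f and fell in dIEC, and 12 did the reverse.

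The last comparison asked whether the response to TNF differed between genotypes. A higher response means a more positive log2 change with TNF, and a lower response a more negative one. Interferon-stimulated genes had a higher response in dIEC, 10 of 31 with 0 lower (22 adjusted over the list alone), with a median difference of 0.47 on the log2 scale. The count was 16 without TNF-treated dIEC library 4. Rsad2, the antiviral enzyme viperin, measured 0.126 and 0.306 FPKM in f/f without and with TNF and 0.157 and 3.75 in dIEC, a difference of 1.78 ± 0.213 (SE, n = 4 per group, adjusted p = 0.000288), and Ifit1 differed by 1.43 ± 0.266 and Usp18 by 1.31 ± 0.232. The list had camera adjusted p = 1.05e-17, and 0.172 with an estimated correlation. Of 4 GTPases 3 had a higher response in dIEC (4 adjusted over the list alone): Irgm1 by 0.61 ± 0.1, Igtp by 0.82 and, named after its value was seen, Irgm2 by 0.61. Without treated dIEC library 2 Igtp had adjusted p = 0.0531 and 1 of 4 was called.

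Enterocyte markers had a lower response in dIEC, 10 of 26 with 0 higher (15 and 1 adjusted over the list alone). For the enterocyte list camera gave adjusted p = 5.87e-20, and 0.0134 with an estimated correlation. Of its genes Lct differed by -1.08 ± 0.102. Fetal-like genes had a higher response in dIEC, 6 of 12 (8 adjusted over the list alone), with the interleukin-1 receptor antagonist Il1rn at 0.92 ± 0.12 and Anxa1 at 0.90 ± 0.142. For the fetal-like list camera gave adjusted p = 1.23e-10, and 0.03 with an estimated correlation. Reg3b differed by -2.23 ± 0.136, having gone from 621 to 157 FPKM in f/f and from 857 to 45.2 in dIEC, and Reg3a differed by -1.49 ± 0.095. The defensins Defa21 and Defa22 rose with TNF in f/f, from 57 to 143 and from 56.1 to 145 FPKM, and went from 53.5 to 43.6 and from 51.5 to 44.8 in dIEC (differences -1.60 and -1.55). S100a6 had a higher response in dIEC (1.24 ± 0.179), the intestinal sphingomyelinase Enpp7 had a lower response (-1.66 ± 0.143), and Fmr1nb, which fell with TNF in f/f, differed by 2.22 ± 0.238.

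Other lists with a different response lost the call with an estimated correlation. Of 25 Paneth genes 4 had a lower response in dIEC (4 adjusted over the list alone), Defa21, Defa22 and, named after their values were seen, Defa20 (-0.72) and Mptx1 (-0.76). For the Paneth list camera gave adjusted p = 2.12e-07, and 0.172 with an estimated correlation. Of 26 NRF2 genes 7 had a higher response (11 adjusted over the list alone), Hmox1 by 1.01 ± 0.139 and Gsta4 by 0.70 ± 0.0859. For the NRF2 list camera gave adjusted p = 6e-09, and 0.0939 with an estimated correlation. Of 22 hypoxia genes 4 had a lower response (7 adjusted over the list alone), Ndrg1 by -0.61 ± 0.0818, Bnip3 by -0.66 ± 0.128 and, named after their values were seen, P4ha1 by -0.40 and Pdk1 by -0.26. The hypoxia count was 2 without unstimulated f/f library 2 or 4, unstimulated dIEC library 1 or 3, f/f library 2 or 3 with TNF, or dIEC library 1, 2 or 3 with TNF, and 7 without unstimulated dIEC library 4. For the hypoxia list camera gave adjusted p = 5.53e-08, and 0.254 with an estimated correlation. Of 29 proliferation genes 2 had a higher response (7 adjusted over the list alone), Ccnb1 (0.28; adjusted p = 0.147 and 0.139 under the other scalings) and Cdk1 (0.24), with 6 without unstimulated f/f library 1. For the proliferation list camera gave adjusted p = 1.56e-07, and 0.0599 with an estimated correlation. Cdk1 was not called without unstimulated f/f library 3 (0.0641), unstimulated dIEC library 2 (0.054), or f/f library 3 (0.0601) and dIEC library 3 (0.0575) with TNF. Of 18 enteroendocrine genes 1 had a higher response (3 adjusted over the list alone), Tph1 (0.43), with 2 without unstimulated dIEC library 2. For the enteroendocrine list camera gave adjusted p = 0.00326, and 0.272 with an estimated correlation. Tph1 was not called without unstimulated f/f libraries 1 (0.056), 2 (0.0709), 3 (0.0559) and 4 (0.0745), unstimulated dIEC libraries 1 (0.0755) and 3 (0.0703), f/f libraries 2 (0.0741) and 4 (0.0778) with TNF, or dIEC libraries 1 (0.0637), 2 (0.0794) and 4 (0.0514) with TNF.

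The autophagy list had a lower response in dIEC with 0 of 35 genes called (0 adjusted over the list alone), a call lost without unstimulated dIEC library 1 (0.0578) or TNF-treated f/f library 4 (0.0519). For the autophagy list the median was -0.05 and camera gave adjusted p = 0.0245, and 0.534 with an estimated correlation. Atg16l1 itself differed by 0.12 (adjusted p = 0.703). Goblet genes had a lower response (1 of 19, Zg16, -0.75 ± 0.129; 1 adjusted over the list alone; 2 without treated f/f library 1), a call lost without unstimulated dIEC library 1 or TNF-treated f/f library 2 (0.0602 each). For the goblet list camera gave adjusted p = 0.0173, and 0.346 with an estimated correlation. Antigen presentation genes had a lower response (2 of 26, Cd74 by -1.22 ± 0.24 and H2-Ab1 by -0.98; 3 adjusted over the list alone; 4 without treated f/f library 1). For the antigen presentation list camera gave adjusted p = 0.0376, and 0.685 with an estimated correlation. With a pseudocount of 5, Cd74 (adjusted p = 0.0537) and H2-Ab1 (0.0908) were not called. That list lost its call without unstimulated f/f library 4 (0.0554), unstimulated dIEC libraries 1 (0.103), 2 (0.0629) and 3 (0.101), f/f libraries 2 (0.131) and 3 (0.121) with TNF, and dIEC libraries 1 (0.0628) and 4 (0.256) with TNF, and also with a pseudocount of 5 (0.0947) or no minimum mean (0.117).

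Not called for the difference were the NF-kB list (2 of 24 higher, 1 lower, 3 and 1 adjusted over the list alone; adjusted p = 0.121, but 0.0441 without TNF-treated f/f library 3, 0.0217 with a pseudocount of 5 and 0.0151 with no minimum mean), with Cxcl16 at 0.56 ± 0.107, Cd83 at -0.61 ± 0.105 and Tnf, named after its value was seen, at 0.46, and the cell death list (1 of 26, Mlkl, 0.59 ± 0.089; 2 adjusted over the list alone; 2 without unstimulated f/f library 1 or dIEC library 2; adjusted p = 0.549). The higher NF-kB genes numbered 1 without unstimulated f/f library 2 or 4, unstimulated dIEC library 1, 2 or 3, f/f library 2 with TNF, or dIEC library 1, 2 or 3 with TNF. The antimicrobial list went both ways, 4 higher and 4 lower of 13 (5 and 4 adjusted over the list alone; 0.257). The lower genes numbered 2 without unstimulated f/f library 4, unstimulated dIEC library 1, 2 or 3, f/f library 2, 3 or 4 with TNF, or dIEC library 1 or 3 with TNF. The called genes were Nos2 (0.90), Duox2 (0.70), Duoxa2 (0.73) and Dmbt1 (0.66) against Reg3a, Reg3b, Reg1 (-0.50) and Ido1 (-0.65), those outside the Reg3 pair named after their values were seen. Also not called were the lysosome (0.639), unfolded protein response (0.581), ATF4 (0.257), cholesterol (0.106), immediate early (0.106), stem (0.562), tuft (0.238) and ribosomal lists (0.416). For the ATF4 and cell death lists the median, mean and test differed in sign. The cholesterol list had a lower response by the call without TNF-treated f/f library 1 (0.0354), with the block nested in genotype (0.0111), with the GC trend removed (0.00647), without the 4 libraries apart on the second component (0.0224) and after quantile normalization (0.0287). The immediate early list was called higher without TNF-treated f/f library 4 (0.0251) or with no minimum mean (0.0117), which also called the tuft list lower (0.00352).

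In all, 365 of 11097 genes had a different response by limma (154 higher, 211 lower in dIEC), 28 of them by at least a doubling or halving, and the count fell to 240 without unstimulated f/f library 4. It was 967 without the 4 libraries apart on the second component. The share of positive differences was 42.2% as deposited and 32.7% after median-of-ratios scaling or 34.9% after quantile normalization. Which direction held more genes depended on the fit: higher responses in dIEC outnumbered lower ones with sample weights (1239 against 681), with the block nested in genotype (701 against 530) and without those 4 libraries (532 against 435), but not with the GC trend removed (369 against 617).

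**Figure D4:**
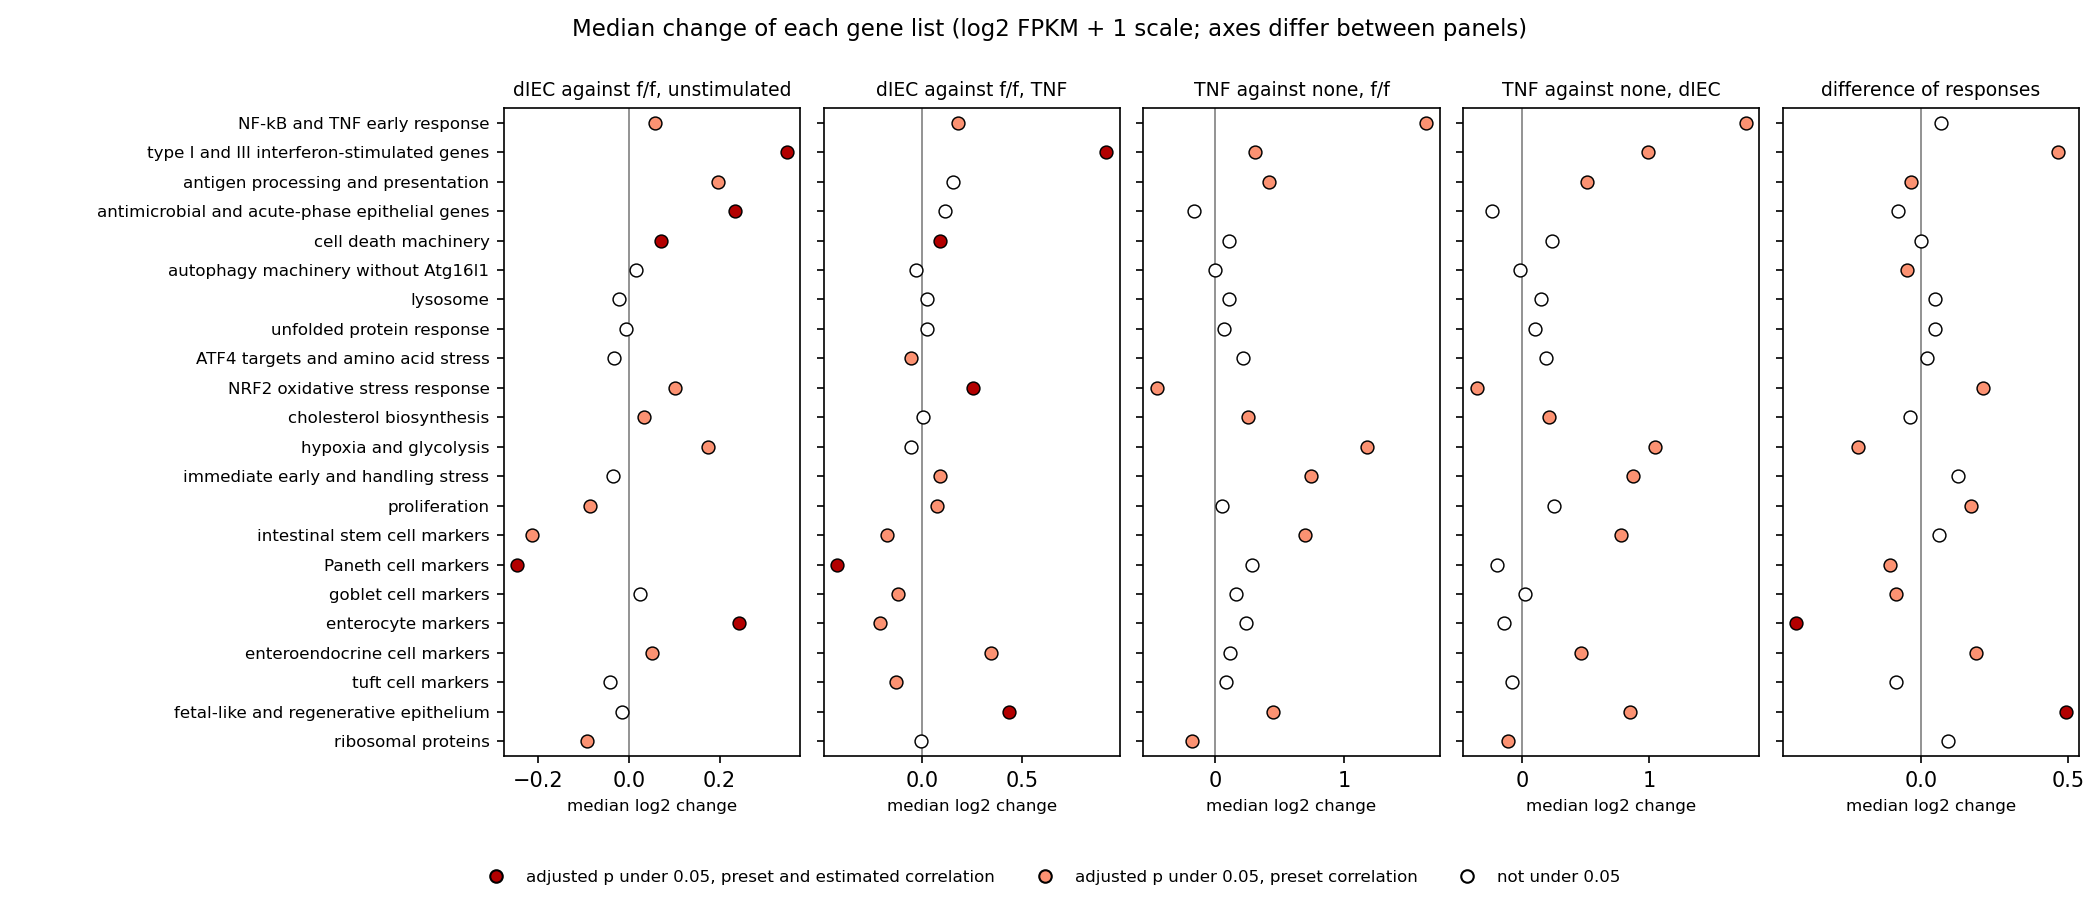
Medians of the log2 change over the kept genes of 22 lists (vertical axis) in the 5 contrasts (horizontal axes, log2 scale). Dark red points have an adjusted p under 0.05 with the preset and with the estimated correlation, light red points with the preset correlation alone, and open points with neither; interferon medians were 0.35 and 0.92 between genotypes without and with TNF.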

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

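The tests of scaling, immune cell RNA, lines or animals, row order, shared runs, genome segments and the defensin cluster, and the relabelling that keeps dIEC pairs, were chosen only after the results were seen.

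Other splits of the same samples show how often regrouping them calls as many genes. For unstimulated dIEC against f/f organoids the real split called 258 genes and the highest other 0, with TNF 721 against 2, and for TNF in f/f 5235 against 1. For TNF in dIEC it called 5897 and the highest other, exchanging unstimulated library 2 with treated library 4, 1458. Each real split was the 1 of 35 as large, the least possible. Mixed groups hold the group difference as spread, so this test cannot exclude chance. For the difference of responses, 2 of 100 drawn relabellings, the real one included, called at least the real 365. The highest other called 1470, so this draw does not exclude chance. That relabelling followed the 4 libraries with a distinct GC trend, which points to that structure, and parted 3 of the 4 numbered dIEC pairs. A further 100, the real one included, kept numbered dIEC pairs together, barring that relabelling, and left f/f libraries free. Only the real one called 365 (highest other 1), but dIEC pairing is not settled, so chance stays open.

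Interferon-stimulated genes were higher in dIEC in both treatments. A scaling between libraries is argued against by the lowest median log2 change of the list under other scalings, 0.34, and a single library by the lowest median without any 1 library, 0.321. RNA of immune cells is argued against as well: the rise of the immune gene sum plus 2 standard errors came to at most 1.33% of the rise of the interferon gene sum. What stays open is whether the difference follows the deletion or the organoid line or animal: 0 samples name one, so these cannot be told apart. That the loss of ATG16L1 raises interferon signalling in these cells may hold as a hypothesis, untested here apart from the comparison itself.

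TNF called about as many genes as it left uncalled, 47.2% in f/f and 53.1% in dIEC. A single scaling factor per library is argued against, since median-of-ratios scaling called at least 95.8% as many. Rows of a repeated symbol may have been joined in another order between the untreated and treated columns, as 7 of 45 such symbols matched better in another order between treatments, by a log2 distance of at least 2, and 0 did so between genotypes. Kept genes of repeated symbols number 118, so this order can account for at most 118 calls, and 15.3% of them in f/f and 16.1% in dIEC were called at a doubling or halving, against 2.55% and 3.43% of the others (Fisher's exact p = 2.2e-09 and 3.29e-08). A run shared by the libraries of a treatment stays open, since 0 labels name one, and it cannot be told apart from TNF. The NF-kB medians, 1.64 and 1.76, were reached by 0 of 10000 random sets matched on level, GC content and length (highest 0.4 and 0.395). That argues against these traits alone, not a run.

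Genes differing the same way between genotypes in both treatments numbered 94, of which 56 lay outside the interferon, GTPase, antigen presentation and Paneth lists, counted once per symbol stem. A passenger region around Atg16l1 is argued against for most of them: 1 lay within 10 Mb, with an upper 95% limit of 9.55% (exact binomial). Of the 56, 21 had another within 2 Mb, against a median of 8 in 10000 random sets, a number 0.1% of those reached, which is consistent with segments of the genome that differ between the lines. Neighbours in the alpha-defensin cluster do not account for it, as 15 of 50 remained close without them (median of random sets 6, reached by 1.24%). Tandem gene families that share reads stay open.

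A sample far from the other 3 of its group was found in 27 of 419 pairs of a printed gene and a group, against 21 expected, as chance yields about 1 in 20. The value is the gap to the nearest sample as a share of the group's range. In unstimulated f/f organoids it was 1 for Zfp280c (library 1, highest), 0.858 for Casp4 (1, highest), 0.99 for Cdca7 (1, lowest), 0.923 for Gsta3 (1, highest), 0.865 for Gsta4 (1, highest), 0.856 for Rnaset2b (2, highest), 0.897 for Fmr1nb (3, lowest) and 0.949 for Cd83 (3, highest). In f/f with TNF it was 0.849 for Mlkl (1, lowest), 0.922 for Muc2 (1, highest), 0.839 for Gsta3 (2, lowest), 0.881 for Spink3 (2, highest), 0.858 for Mir684-1 (3, highest), 0.863 for Reg3a (3, highest), 1 for Zfp280c (4, highest) and 0.848 for Dusp1 (4, highest). In unstimulated dIEC organoids it was 0.923 for Mir684-1 (1, highest), 0.849 for Cybrd1 (1, highest), 0.885 for Fmr1nb (2, highest), 0.875 for Nos2 (3, lowest), 0.833 for Ifi27l1 (4, lowest), 0.862 for Cd74 (4, lowest), 0.84 for Gcg (4, lowest) and 0.84 for Anxa1 (4, highest). In dIEC with TNF it was 0.893 for Gabarapl1 (4, lowest), 0.91 for Mir684-1 (4, highest) and 0.853 for Cd83 (4, highest).

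By limma's test of the difference, the TNF response differed for 43 of 130 printed genes, some chosen by it, and 365 of all 11097. Higher in dIEC, on the log2 scale, were the responses of Fmr1nb (2.22), Rsad2 (1.78), Ifit3 (1.72), Slfn2 (1.60), Ifit1 (1.43), Ifi27l2a (1.40), Usp18 (1.31), S100a6 (1.24), Ly6a (1.09), Hmox1 (1.01), Il1rn (0.92), Anxa1 (0.90), Nos2 (0.90), Igtp (0.82), Cxcl10 (0.71), Gsta4 (0.70), Irgm2 (0.61), Irgm1 (0.61), Mlkl (0.59), Cxcl16 (0.56), Ly6e (0.53), Tnf (0.46), Tph1 (0.43), Srxn1 (0.33), Ccnb1 (0.28) and Cdk1 (0.24). Lower were those of Reg3b (-2.23), Enpp7 (-1.66), Defa21 (-1.60), Defa22 (-1.55), Reg3a (-1.49), Pcp4l1 (-1.31), Spink3 (-1.27), Cd74 (-1.22), Lct (-1.08), H2-Ab1 (-0.98), Mptx1 (-0.76), Zg16 (-0.75), Bnip3 (-0.66), Cd83 (-0.61), Ndrg1 (-0.61), Krt20 (-0.42) and Vldlr (-0.33). Leaving out 1 library ended some calls, with these limma adjusted p-values. Without treated dIEC library 2 they were 0.0531 for Igtp, 0.0536 for Ifi27l2a, 0.0593 for Irgm2, 0.0509 for Tnf and 0.0794 for Tph1, and without unstimulated dIEC library 2 0.0509 for Ifi27l2a, 0.0503 for Irgm2, 0.0616 for Tnf and 0.054 for Cdk1. Irgm2 was also lost without unstimulated f/f library 2 (0.0501), treated f/f library 4 (0.0529) or treated dIEC library 3 (0.0512), and Cdk1 without f/f library 3, unstimulated (0.0641) or treated (0.0601), or treated dIEC library 3 (0.0575). Tnf was also lost without unstimulated f/f library 2 (0.0645) or 4 (0.0757), unstimulated dIEC library 1 (0.07) or 3 (0.0639), treated f/f library 2 (0.0547) and treated dIEC library 1 (0.0589) or 3 (0.0762). Tph1 was also lost without unstimulated f/f libraries 1 (0.056), 2 (0.0709), 3 (0.0559) or 4 (0.0745), unstimulated dIEC libraries 1 (0.0755) or 3 (0.0703), treated f/f libraries 2 (0.0741) or 4 (0.0778) and treated dIEC libraries 1 (0.0637) or 4 (0.0514).

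By camera, 11 lists had a different response with the preset correlation, and of them the enterocyte and fetal-like lists also with an estimated one. Higher in dIEC were the interferon (adjusted p = 1.05e-17), fetal-like (1.23e-10), NRF2 (6e-09), proliferation (1.56e-07) and enteroendocrine lists (0.00326). Lower were the enterocyte (5.87e-20), hypoxia (5.53e-08), Paneth (2.12e-07), goblet (0.0173), autophagy (0.0245) and antigen presentation lists (0.0376). The call of the goblet list was lost without unstimulated dIEC library 1 or treated f/f library 2 (0.0602 each), and that of the autophagy list without unstimulated dIEC library 1 (0.0578) or treated f/f library 4 (0.0519). That of antigen presentation was lost without unstimulated f/f library 4 (0.0554), unstimulated dIEC libraries 1 (0.103), 2 (0.0629) or 3 (0.101), treated f/f libraries 2 (0.131) or 3 (0.121) and treated dIEC libraries 1 (0.0628) or 4 (0.256).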

How the results depend on the processing

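The summed rows, the omission of small RNA genes, the nested block, the omission of 4 libraries (f/f 1 and dIEC 4 of each treatment) and the removal of the GC trend were chosen after the data were seen, and tests on counts were not run because the values are FPKM, from which no whole reads were recovered. Depth is unknown, so what it limits cannot be stated. Between genotypes Atg16l1 kept its direction and call under the alternatives in which it was tested; the minimum log2 change of 1, which it did not reach, was not among them. Where no cause follows from the alternative itself, the cause was not tested. In the order dIEC against f/f without TNF, with TNF, TNF in f/f, TNF in dIEC and the difference of responses, the counts of called genes were 258, 721, 5235, 5897 and 365. Counts not given below stayed within 1.5 times these. A mean of at least 5 FPKM, which tests fewer genes, gave 166 without TNF, 449 with TNF and 195 for the difference, and no minimum gave 1082 with TNF. Sample weights gave 1781, 2556 and 1920 for those contrasts. A fit of only the 8 samples, with fewer samples for the spread, gave 136 without TNF. Requiring a log2 change of at least 1 left 19, 54, 298, 396 and 28. Leaving out the 4 libraries gave 709, 1505 and 967 for the genotype contrasts and the difference, and removing the GC trend 686, 1694 and 986. The replicate block gave 306, 878, 5624, 6316 and 443, all within 1.5 times, and ended the list calls of immediate early (adjusted p = 0.0678) and tuft genes (0.0517) between genotypes with TNF. Nested in genotype it gave 1231 for the difference. Below, a named result is a named gene in 1 contrast, and it keeps its call also by staying uncalled. With the replicate block 356 of 366 named results kept their call, 4 lost it and 6 gained it, and for TNF in dIEC the proliferation and enterocyte lists gained it (0.0373 each); it changed no other list call. Lists called with an estimated correlation were 5, 5, 0, 0 and 2, against 14, 14, 10, 11 and 11.

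Leaving out each library in turn, the count ranged from 139 (without unstimulated f/f library 2) to 304 (without treated f/f library 1) for dIEC against f/f without TNF, and from 240 (without unstimulated f/f library 4) to 450 (without unstimulated dIEC library 4) for the difference. Without TNF it was also low without unstimulated f/f libraries 3 (140) and 4 (142) and dIEC libraries 1 (141) and 2 (153). The adjusted p of the ribosomal list without TNF ranged from 0.000103 (without unstimulated dIEC library 3) to 0.686 (without library 4, where it turned up), and its call was lost without unstimulated f/f library 1 (0.173) or dIEC library 2 (0.117). Over these fits, 5627 of 5856 named results kept direction and call, 200 lost the call and 29 gained it, and 918 of 960 for lists kept it. The ribosomal list also turned without the 4 libraries (0.363, dIEC against f/f without TNF) and after quantile normalization (0.661 for TNF in f/f, 0.143 in dIEC), which reversed Rps4x (log2 change 0.034) and Rpl10 (0.0264) for TNF in dIEC. Rpl32 turned to a log2 change of 0.0167 between genotypes without TNF under sample weights. One summed row per symbol turned the TNF changes of Mir684-1 (log2 -0.289 in f/f, -0.227 in dIEC) and Rnaset2b (-0.127 and -0.132), because rows of a symbol are then added. Of 366 named results, 347 kept direction and call after median-of-ratios scaling, 335 after quantile normalization, 324 with sample weights and 334 without the 4 libraries.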

Other observations

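All tests in this part, of overlaps, scores and the authors' p-value columns, were chosen after the results were seen, and no explanation was tested.

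Genes that differed between genotypes in both treatments went mostly the same way. Of 171 genes higher in unstimulated dIEC organoids, 51 were higher with TNF too (6.49 expected of independent lists), and of 87 lower ones 43 were lower with TNF too (2.35 expected). These contrasts share no library. A further 33 genes were higher without TNF and lower with it (4.62 expected), and 3 the reverse (3.30 expected). Reg3a and Reg3b, lectins of the antimicrobial list, were among the 33, at log2 changes of 0.61 and 0.46 without TNF and -0.88 and -1.77 with it, as was the enterocyte gene Lct (0.32 and -0.76); these 3 were picked for this comparison after their values were seen.

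Enterocyte scores, the mean log2 value of the kept markers per library, were 6.76 ± 0.07 in f/f and 7.00 ± 0.06 in dIEC without TNF, and 7.05 ± 0.06 and 6.89 ± 0.07 with it (SD, n = 4). All 4 values of one genotype lay apart from those of the other in each treatment (exact two-sided permutation test, p = 0.0286 each, the smallest possible).

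The authors' deposited table holds 3 columns of p-values. In the authors' deposited table the values of the first and second column equal those of an unequal-variance test between the groups their names give, within 1% in 100% of 18856 and 18995 genes. Those of the third column of the authors' deposited table, named for dIEC against f/f with TNF, did so for 2.71% of 18943 genes. In the authors' deposited table they equal the test of columns 8 to 11 against columns 12 to 16 in 100% of 19068 genes, a division that puts 1 unstimulated dIEC library and 3 of the 4 treated f/f libraries on one side and the remaining treated f/f library with the treated dIEC libraries on the other.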
